A study of Mus musculus with 71 samples.

How the data were processed

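Whole-brain RNA of male mice of the strains AKR/J, C57BL/6J and DBA/2J was measured on 71 one-colour Affymetrix arrays, each with a pool of RNA from 3 mice of 1 group. The groups were 3 strains, 2 conditions (6 h of sleep deprivation ending at sacrifice, or an undisturbed home cage) and 4 times of sacrifice, 24 in all, taken from the sample labels. Each group held 3 arrays apart from sleep-deprived AKR/J at ZT18 with 2. The design text names 9 mice per group, so the arrays of a group are pools of different mice, and p-values measure the spread between pools.

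The deposited values are log2 expression levels per probe set, which the authors made with RMA per the submitters' processing notes. The RMA version, its settings and the scanner software are not given in the sources used here, and scanner files were not used here. The log2 scale was checked on the values, which run from 2.69 to 14.8, with array medians from 5.65 to 5.71. Arrays correlated at 0.986 or more with each other. Replicate arrays of a group differed by a root mean square of 0.145 to 0.239 log2 units, so none was treated as a repeat deposit. No counts or detection calls underlie these values, and precision is limited by the number of arrays.

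Of 45101 probe sets, 64 control probe sets were left out and 45037 tested. Gene names came from the platform annotation: 34945 probe sets had 1 symbol, 932 several and 9160 none here, for 18193 symbols. Symbols were updated through Entrez IDs, of which those of 34741 probe sets were found in a RefSeq gene list of assembly GRCm38.p6. That list served for names only, and since no source used here names the build of the probes, no coordinates are given. Probe sets ending in _x_at or _s_at can match several transcripts and are said to be such.

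A cell-means model of the 24 groups was fitted to all 71 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with the package data.table in version 1.17.8 for reading. All groups shared 1 estimate of the spread with 47 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all probe sets tested, and a probe set was called at an adjusted p under 0.05. Sleep deprivation was tested as the mean of the 12 differences within strain and time, within each strain, and at each time. The response shared by the 3 strains required a call and the same sign in each strain. F tests were used for strain by sleep deprivation, time by sleep deprivation, and time of day in controls and in sleep-deprived mice; for these the text gives the range between fitted effects. Strain differences were tested in controls over the 4 times.

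Gene lists were fixed before the data were examined: study genes, immediate early and activity-regulated genes, core clock and clock output genes, cytosolic heat shock proteins and cochaperones, endoplasmic reticulum stress, cold-inducible RNA-binding proteins, glucocorticoid-responsive genes, cholesterol and fatty acid synthesis, glucose transport with glycolysis and glycogen, mitochondrial respiratory chain, aminoacyl-tRNA synthetases, glutamate receptors, GABA receptors, potassium channels, and sleep-wake neuromodulators. Marker lists covered neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial cells, choroid plexus, blood cells, meninges, pituitary, cerebellum, striatum, hypothalamus and olfactory bulb. Of 530 listed genes 488 were measured, each on its probe set of highest mean. The lists were tested against other genes with camera at a preset correlation of 0.01, and with estimated correlation as an alternative. For the F tests, Fisher's exact test compared the share of called members with that of other genes. It treats genes as independent and was not set against other splits of the arrays, so its p-values can be too small.

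The named-gene rule was also fixed before the data were examined. For each comparison of 2 conditions or strains it takes the 10 largest rises and the 10 largest falls among called probe sets with 1 symbol, 1 probe set per gene with the smallest p, and for the overall effect the same sign in the 3 strains. It takes every probe set of Homer1, Ptgs2, Jph3 and Nptx2, up to 4 members per list with the smallest p, and lists of 3 genes or fewer in full. For F tests it takes the 10 smallest p and the list members.

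The design and the tests of the group comparisons were set before the data were examined. The alternatives set beforehand were quantile normalization, centring on array medians, only probe sets above the median level, trend and robust eBayes, array weights, a replicate block, 1 probe set per gene, a minimum change of 0.25 log2, only the compared groups in the fit, an additive model, cosine terms, fry, the mean of all probe sets of a gene, and leaving out each array. Alternatives chosen after seeing the data were a spike-in batch as a block, leaving out the 6 arrays of that batch, and pituitary hormone genes as a covariate. The sleep deprivation score with the tests of the few calls at ZT18, the ratio of variances between times and the comparison of falls at ZT6 with AKR/J were also chosen then. So were the count of lists called with an estimated correlation over other splits and the comparison of single lists over those splits. The batch was found on 45 spike-in control probe sets, where the 6 arrays lay 1.99 score units from the nearest of the other 65. The next largest gap was 0.596. The 6 arrays also lay apart on the 3' minus 5' signal of the mouse gene Gapdh, at -0.121 or higher against -0.155 or lower in the other 65. The AKR/J arrays among them were controls only, at ZT0 and ZT6, and none was of DBA/2J. No label gives a batch.

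The steps were tested on simulated data with the real means and spread on 45037 probe sets, with 50 probe sets changed at each size. At 0.2 log2 units, 96% were recovered for the overall sleep deprivation effect, 48%, 56% and 54% for AKR/J, C57BL/6J and DBA/2J, 30% for the shared response, and 42%, 52%, 38% and 38% for ZT0, ZT6, ZT12 and ZT18. Recovery at that size was 26% for strain by sleep deprivation, 10% for time by sleep deprivation, 38% for time of day in controls and 52% in sleep-deprived mice. At 0.5 log2 units it was 94% for time by sleep deprivation and 100% for the overall effect. False calls made up from 0% of the calls, for the shared response, to 7%, in DBA/2J. The noise was drawn independently for each probe set, and fewer probe sets changed than were called in the real data. Recovery there may thus differ. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.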

Results

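RNA levels in whole brain were measured in male mice of 3 inbred strains, AKR/J, C57BL/6J and DBA/2J, that had been kept awake for 6 h or left undisturbed in the home cage. Mice were killed at 4 times of day, ZT0, ZT6, ZT12 and ZT18, where ZT is the time in hours after light onset and the dark phase began at ZT12. Each Affymetrix mouse expression array carried RNA pooled from 3 mice. Of the 24 groups of strain, treatment and time, 23 held 3 arrays and the sleep-deprived AKR/J group at ZT18 held 2, which gave 36 control and 35 sleep-deprived arrays. The study asked how sleep loss changes brain RNA, and whether strain and time of day alter that response. Values are log2 signal per probe set, so a difference of 1 is a doubling. The number of arrays limits the precision of every value.

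After sleep deprivation, brain RNA of activity-regulated genes and of protein chaperones was higher in all 3 strains. Homer1, whose short activity-induced form acts at excitatory synapses, showed the largest rise, 1.57 ± 0.03 log2 units (SE, 71 arrays, 2.96-fold; limma adjusted p = 1.85e-41) on the most responsive of its 6 probe sets, which the Homer1 values of the later comparisons refer to. The inducible chaperone gene Hspa1b rose by 1.24 ± 0.06 on an _x_at probe set, which can match several transcripts. Cirbp, an RNA-binding protein gene that is induced by cold, fell by 0.69 ± 0.03 and Opalin, a myelin protein gene of oligodendrocytes, fell by 0.59 ± 0.03. In all, 7795 of 45037 probe sets differed at an adjusted p under 0.05, 3743 higher and 4052 lower, from 5031 named genes. Most changes were small: the median size among them was 0.11 log2 units, and 356 reached 0.25.

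Among the 10 largest rises, Egr2 and Egr3, zinc finger transcription factors of the immediate early class, rose by 0.97 ± 0.05 (adjusted p = 1.71e-21) and 0.69 ± 0.03 (adjusted p = 2.99e-28). Arc, a synaptic immediate early gene, rose by 0.95 ± 0.05, and the AP-1 genes Fosl2 and Fos rose by 0.83 ± 0.04 and 0.79 ± 0.05. Hspb1, a small heat shock protein gene, rose by 0.80 ± 0.07 on an _x_at probe set. Gm19439 rose by 0.72 ± 0.05. Sdf2l1, an endoplasmic reticulum chaperone gene, rose by 0.68 ± 0.05. Each of these was higher in all 12 strain-by-time comparisons. Among the 10 largest falls were Rprd2 on an _s_at probe set (-0.56 ± 0.04), 4930570G19Rik (-0.46 ± 0.04), 0610040B10Rik (-0.45 ± 0.04), the organic anion transporter gene Slc22a8 (-0.42 ± 0.03) and the clock output gene Dbp (-0.41 ± 0.03). Krt12, a keratin gene, fell by 0.38 ± 0.03, and Tfrc, the transferrin receptor gene, fell by 0.36 ± 0.02. Btg1, a member of the immediate early list, fell by 0.42 ± 0.05 on 1 probe set, whereas its other probe set, the brighter one used for the list, gave 0.02.

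The study's own 4 genes were measured on every probe set. All 6 Homer1 probe sets rose, the other 5 by 0.83, 0.29, 0.19, 0.18 and 0.15. Ptgs2, the gene of cyclooxygenase 2, rose by 0.68 and 0.38 on its pair of probe sets. Nptx2, a neuronal pentraxin gene, rose by 0.41 and 0.18. Jph3, a junctophilin gene, rose by 0.24 on 1 probe set and gave -0.04 (adjusted p = 0.497) on the brighter one. As a list on the brightest probe set per gene, 3 of the 4 rose and none fell, 3 also when adjusted over the list alone (camera adjusted p = 9.27e-05). The study chose these genes, so the list is not independent evidence of their direction.

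Of 50 immediate early and activity-regulated genes, 39 rose and 2 fell (41 and 2 adjusted over the list alone; camera adjusted p = 2.76e-48). Bdnf, a neurotrophin gene, rose by 0.57 (adjusted p = 4.44e-23) and the nuclear receptor gene Nr4a3 by 0.52 (adjusted p = 5.44e-23). The 2 members that fell, named after their values were seen, were Jun (-0.09) and Jund (-0.07), which encode AP-1 subunits. Btg1, also a member, was counted on its brighter probe set and not on the one that fell. Of 36 cytosolic heat shock proteins and cochaperones, 28 rose and none fell (30 adjusted over the list alone; camera adjusted p = 2.18e-39). Chordc1 rose by 0.47, Hsph1 by 0.37, Ahsa1 by 0.26 and Dnajb5, on an _s_at probe set, by 0.35. Of 33 endoplasmic reticulum stress genes, 26 rose and none fell (28 up and 1 down adjusted over the list alone; camera adjusted p = 2.4e-35). Hspa5, which encodes the chaperone BiP, rose by 0.67, Creld2 by 0.63, Manf by 0.61 and the disulfide isomerase gene Pdia6 by 0.50.

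Of 24 glucocorticoid-responsive genes, 22 rose and none fell (22 adjusted over the list alone; camera adjusted p = 6.43e-27). Cdkn1a, a cell cycle inhibitor gene, rose by 0.58, Tsc22d3 and the phosphatase gene Dusp1 by 0.40 each, and Gjb6, which encodes connexin 30, by 0.28. Cdkn1a, Dusp1 and Per1 were on the immediate early list too, so these lists are not wholly separate evidence. Cholesterol and fatty acid synthesis went the other way, with 15 of 27 members lower and 2 higher (18 and 2 adjusted over the list alone; camera adjusted p = 2.56e-06). Lss, lanosterol synthase, fell by 0.31 (adjusted p = 2.69e-11), Insig1 by 0.25, Srebf1, a regulator of lipid synthesis, by 0.16 and the squalene epoxidase gene Sqle by 0.13. The members that rose, named after their values were seen, were Elovl6 (0.12) and Ebp (0.11). Among 34 sleep-wake neuromodulators and neuropeptides, 8 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00202). Crh, corticotropin-releasing hormone, rose by 0.53, Nts, neurotensin, by 0.33, Vip by 0.20 and Cck by 0.09.

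Of 9 oligodendrocyte markers, 4 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0358). That call was lost with an estimated correlation (adjusted p = 0.449). Besides Opalin, Mag fell by 0.10, Mog by 0.12 and Cnp, on an _x_at probe set, by 0.07. The core clock list had 7 members up and 7 down of 23 (7 and 10 adjusted over the list alone; camera adjusted p = 0.752), with a median of -0.04 and a mean of 0.01. In it Per2 rose by 0.43, Nfil3 by 0.34 and Arntl, a core clock activator, by 0.18. Of 30 glucose transport, glycolysis and glycogen genes, 5 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.302). Those up included the glucose transporter gene Slc2a1 (0.18), Pfkfb3 (0.30), Ppp1r3c (0.18) and Ldha (0.10).

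The remaining lists did not pass camera's test. Members up and down were 4 and 1 of 34 mitochondrial respiratory chain genes (adjusted p = 0.474), 2 and 3 of 19 aminoacyl-tRNA synthetases (adjusted p = 0.931), and 2 and 7 of 31 glutamate receptor and postsynaptic genes (adjusted p = 0.372). They were 1 and 2 of 15 GABA receptor and inhibitory synapse genes (adjusted p = 0.554) and 4 and 4 of 34 potassium channels (adjusted p = 0.752). Cell type markers gave 1 and 1 of 10 for neurons (adjusted p = 0.726), 1 and 0 of 10 for astrocytes (adjusted p = 0.551), 2 and 1 of 7 for oligodendrocyte precursors (adjusted p = 0.237), 2 and 1 of 10 for microglia (adjusted p = 0.931) and 1 and 2 of 9 for endothelial cells (adjusted p = 0.726). Tissue markers gave 1 and 0 of 9 for choroid plexus (adjusted p = 0.931), 0 and 0 of 6 for blood cells (adjusted p = 0.931), 0 and 2 of 9 for meninges (adjusted p = 0.302) and 0 and 2 of 9 for cerebellum (adjusted p = 0.752). They gave 1 and 0 of 7 for striatum (adjusted p = 0.931), 2 and 0 of 7 for hypothalamus (adjusted p = 0.161) and 1 and 0 of 6 for olfactory bulb (adjusted p = 0.474). None of 5 pituitary hormone genes passed the test; their median was -0.39 (camera adjusted p = 0.717), and Gh ranged from 4.19 to 13.3 log2 units across arrays, under 7 in 3 control and 5 sleep-deprived arrays. The cold-inducible RNA-binding protein list had only Cirbp measured and was not tested as a list. Median and mean differed in sign for the clock, astrocyte and cerebellum lists, and the test's direction was up while both lay below 0 for the choroid plexus and striatum lists.

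Of the lists, 8 passed with camera's preset correlation and 7 with an estimated one, and other splits of the arrays called up to 12 lists with the preset correlation and up to 1 with the estimated one. Single lists were set against the splits after that count was seen. Other splits called the immediate early list 47 times, heat shock 44 and glucocorticoid-responsive genes 48, none with as small a p. Cholesterol synthesis was called in 28 others, and 3 of 100 splits, the real one included, had as small a camera adjusted p. With an estimated correlation (adjusted p = 0.0112) only its real split was as small. For the oligodendrocyte list 10 of 100 splits, the real one included, had as small a camera adjusted p, with the preset and with the estimated correlation. The sleep-wake list had a camera adjusted p of 0.00202, against 0.00282 in the nearest other split with the preset correlation. Preset p-values of single lists are thus too small at face value. A group of 6 arrays stood apart on spike-in controls. With this batch as a block 8977 probe sets differed, and 7805 in the other 65 arrays. The 6 arrays were few and were not tested alone.

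**Figure D1:**
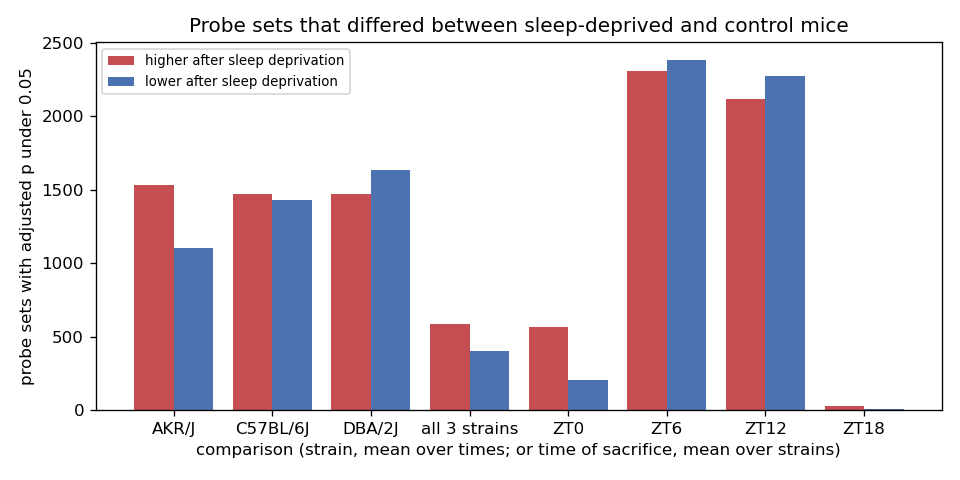
Bars give the number of probe sets, in counts, that were higher (red) or lower (blue) after sleep deprivation at an adjusted p under 0.05 within each strain (mean over times), in all 3 strains, and at each time of sacrifice (mean over strains). The count was 4693 at ZT6, 4391 at ZT12, 770 at ZT0 and 35 at ZT18.

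Each strain on its own showed the Homer1 rise, of 1.68 ± 0.06 log2 units in AKR/J (SE; limma adjusted p = 4.7e-30), 1.39 ± 0.06 in C57BL/6J (adjusted p = 1.15e-26) and 1.63 ± 0.06 in DBA/2J (adjusted p = 3.87e-30). Hspa1b rose by 1.34, 0.98 and 1.41 in the same order, on an _x_at probe set, and Arc by 0.97, 0.86 and 1.03. Cirbp fell by 0.59, 0.73 and 0.75, and Opalin fell by 0.48, 0.69 and 0.60. In AKR/J, 2635 probe sets differed (1533 higher, 1102 lower), in C57BL/6J 2907 (1474 higher, 1433 lower) and in DBA/2J 3106 (1472 higher, 1634 lower).

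In AKR/J mice, Egr2 rose by 1.11, Ptgs2 by 1.04, Egr3 by 0.86, Fosl2 by 0.85, Sdf2l1 by 0.84, Fos by 0.83 and Hspb1, on an _x_at probe set, by 0.82. The largest falls besides Cirbp and Opalin were Rprd2 on an _s_at probe set (-0.52), 4930570G19Rik (-0.46), Dbp on an _s_at probe set (-0.42), Mrpl15 on an _x_at probe set (-0.41), Arglu1 (-0.40), Btg1 (-0.39), Slc22a8 (-0.39) and Zfand4 (-0.38). Of the lists, immediate early genes had 33 members up and 1 down of 50 (37 and 1 adjusted over the list alone; camera adjusted p = 2.39e-49), heat shock 27 up of 36 (28 adjusted over the list alone), endoplasmic reticulum stress 22 of 33 (23 adjusted over the list alone) and glucocorticoid-responsive genes 12 of 24 (15 adjusted over the list alone). Cholesterol synthesis had 5 members down and 1 up of 27 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0343), a call lost with an estimated correlation (adjusted p = 0.412). The glucose, glutamate receptor, sleep-wake and oligodendrocyte lists also passed in AKR/J and lost the call with an estimated correlation (adjusted p = 0.337, 0.695, 0.16 and 0.467). With the spike-in batch as a block 2718 probe sets differed in AKR/J, and 2428 in the other 65 arrays.

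In C57BL/6J mice, Gm19439 rose by 0.84, Fosl2 by 0.81, Egr2 by 0.80, Hspb1 on an _x_at probe set by 0.76, Ptgs2 and Zmym1 by 0.72 each and Cdkn1a by 0.69. Falls included Rprd2 on an _s_at probe set (-0.59), Gkn3 (-0.56), Dbp (-0.55), 0610040B10Rik (-0.54), Nxpe4 (-0.49), the phospholipase gene Pla2g4e (-0.49), C920006O11Rik (-0.48) and G530011O06Rik (-0.47). Immediate early genes had 33 of 50 members up (35 up and 1 down adjusted over the list alone; camera adjusted p = 2.6e-36), heat shock 22 of 36 (24 adjusted over the list alone), endoplasmic reticulum stress 19 of 33 (22 adjusted over the list alone) and glucocorticoid-responsive genes 20 of 24 (22 adjusted over the list alone). Of 27 cholesterol synthesis genes 12 fell (16 down and 1 up adjusted over the list alone; camera adjusted p = 1.47e-09, 0.000965 with an estimated correlation). The sleep-wake list passed with the preset correlation and not with an estimated one (adjusted p = 0.0988). The C57BL/6J count was 3046 with the spike-in batch as a block and 1889 without the 6 arrays, 4 of which are C57BL/6J arrays. With array weights it was 4998. In sleep-deprived C57BL/6J at ZT6 the weights were 0.711 and 1.81 for the arrays that stood apart and 0.403 for the other one. The rest of the 6 arrays had weights from 0.359 to 0.389.

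In DBA/2J mice, Egr2 rose by 1.01, Fos by 0.92, Fosl2 by 0.83, Hspb1 on an _x_at probe set by 0.80, Gm19439 by 0.72, and Hspa1a and Egr3 by 0.70 each. Falls included 4930570G19Rik (-0.72), Rprd2 on an _s_at probe set (-0.58), Zfp810 (-0.50), Fam71e1 on an _x_at probe set (-0.45), Eif2s3y (-0.44), the kinase gene Tnik (-0.44), 0610040B10Rik (-0.43) and Slc22a8 (-0.43). Ptgs2 rose by 0.28 on 1 probe set (adjusted p = 0.0387), a call that ended with any of 13 arrays left out in turn (highest adjusted p = 0.116, without DBA/2J control ZT6 replicate 3) or with only the compared groups in the fit (adjusted p = 0.0844), and gave 0.09 on the other (adjusted p = 0.65). Immediate early genes had 36 of 50 members up (39 adjusted over the list alone; camera adjusted p = 1.86e-50), heat shock 24 of 36 (27 adjusted over the list alone), endoplasmic reticulum stress 19 of 33 (22 adjusted over the list alone) and glucocorticoid-responsive genes 14 of 24 (21 adjusted over the list alone). Cholesterol synthesis had 7 members down and 2 up of 27 (15 and 2 adjusted over the list alone; camera adjusted p = 9.49e-05). The oligodendrocyte list lost its call with an estimated correlation (adjusted p = 0.351). The count was 4024 with the spike-in batch as a block and 3886 in the other 65 arrays.

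The response shared by the 3 strains comprised 986 probe sets called in every strain with the same sign, 586 higher and 400 lower. Independent lists would share 1.64 and 1.27 if each probe set were equally likely to be called, which was not tested. No probe set was called with opposite signs in 2 strains. By mean size over the strains, the largest shared rises were those of Homer1, Hspa1b (an _x_at probe set), Egr2, Arc, Fosl2, Hspb1 (an _x_at probe set) and Fos. The largest shared falls were those of Cirbp, whose highest strain adjusted p was 1.3e-10, Opalin (2.76e-10) and Rprd2 on an _s_at probe set (1.81e-07). Across probe sets, which are not independent replicates, the strain effects correlated at r = 0.412 (AKR/J and C57BL/6J), 0.557 (AKR/J and DBA/2J) and 0.604 (C57BL/6J and DBA/2J). The shared count was 1283 with the spike-in batch as a block and 983 in the other 65 arrays.

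The test of strain by sleep deprivation, which asks whether the response itself differs between strains, called 10 probe sets from 8 genes. Gabra2, a GABA receptor subunit gene, rose by 0.31 in C57BL/6J (adjusted p = 4.02e-09) and gave 0.00 in AKR/J (adjusted p = 0.981) and -0.02 in DBA/2J (adjusted p = 0.863); the limma adjusted p of the difference was 0.000369. Ptgs2 changed by 1.04, 0.72 and 0.28 in AKR/J, C57BL/6J and DBA/2J (adjusted p of the difference = 0.00999). Pla2g4e fell by 0.49 in C57BL/6J and by 0.19 in DBA/2J, with -0.02 in AKR/J (adjusted p of the difference = 0.0191). Mcm6, a replication helicase gene, on an _x_at probe set, fell by 0.32 in C57BL/6J and gave 0.01 and -0.06 in AKR/J and DBA/2J (adjusted p of the difference = 0.0237). Rbm28 rose by 0.37 in C57BL/6J and by 0.14 in DBA/2J, with 0.12 in AKR/J (adjusted p of the difference = 0.0367). The other genes were 4930570G19Rik (-0.46, -0.21 and -0.72; adjusted p of the difference = 0.0237), 1500004A13Rik (0.37, 0.07 and -0.05; 0.0237) and 4930578G10Rik (0.48, 0.11 and 0.00; 0.0367). The study gene list held 1 of these, Ptgs2, of 4 members (1 adjusted over the list alone; Fisher's exact test adjusted p = 0.0383), and it was chosen by the study. The count was 16 after quantile normalization, 60 with array weights, 18 with the pituitary covariate and 6 to 25 with 1 array left out. With arrays left out in turn, the calls of 4930570G19Rik, 1500004A13Rik, 4930578G10Rik and Rbm28 ended without any of 2, 4, 21 and 27 arrays (highest adjusted p = 0.0536, 0.0898, 0.148 and 0.0788). The calls of Pla2g4e, Mcm6 on its _x_at probe set and Rbm28 ended with the spike-in batch as a block (adjusted p = 0.0656 each), where 11 probe sets were called, against 8 in the other 65 arrays.

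**Figure D2:**
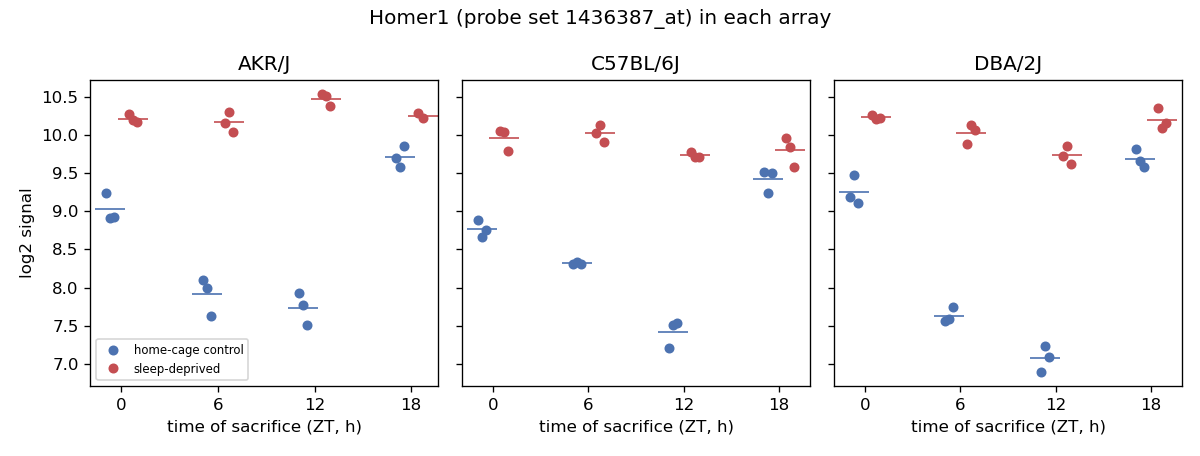
Each point is 1 array and each horizontal bar a group mean of the log2 signal of Homer1 on its most responsive probe set, against time of sacrifice (ZT, h), in home-cage controls (blue) and sleep-deprived mice (red) of each strain. The sleep-deprived arrays sit between 9.58 and 10.5, and the controls range from 6.90 to 9.85.

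The size of the response depended on the time at which sleep deprivation ended. Homer1 rose by 1.12 ± 0.07 at ZT0 (SE; limma adjusted p = 5.47e-19), 2.11 at ZT6 (adjusted p = 1.13e-32), 2.57 at ZT12 (adjusted p = 4.24e-37) and 0.48 at ZT18 (adjusted p = 0.000146). Its control mean was 9.02 ± 0.17 (SD within strain, n = 9) at ZT0, 7.96 ± 0.15 at ZT6, 7.41 ± 0.19 at ZT12 and 9.60 ± 0.14 at ZT18, whereas its sleep-deprived mean was 10.13 ± 0.09, 10.07 ± 0.12, 9.98 ± 0.09 and, with n = 8, 10.08 ± 0.15. Cirbp had control means of 7.45, 8.36, 8.30 and 7.40 and sleep-deprived means of 6.95, 7.08, 7.46 and 7.26 at the same times.

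At ZT0, 770 probe sets differed, 566 higher and 204 lower. Among the 10 largest rises, which Homer1 led, Hspa1b and Hspb1 rose by 1.00 and 0.71 on _x_at probe sets, Creld2 by 0.60, Sdf2l1 by 0.59, Xbp1, a transcription factor of the unfolded protein response, by 0.57 on an _s_at probe set, and Manf by 0.56. Egr2 rose by 0.60, Npas4, an activity-regulated transcription factor gene, by 0.58 and Fosl2 by 0.57. Falls included Cirbp (-0.50), 4930570G19Rik (-0.36), Opalin (-0.36), Dbp on an _s_at probe set (-0.34), Mfsd4a (-0.33), Bace2 on an _x_at probe set (-0.32), Dido1 (-0.32) and 4933431E20Rik (-0.28). Heat shock genes had 20 of 36 members up (28 adjusted over the list alone; camera adjusted p = 8.58e-40), immediate early genes 18 of 50 (31 up and 1 down adjusted over the list alone) and endoplasmic reticulum stress genes 16 of 33 (21 up and 1 down adjusted over the list alone). Glucocorticoid-responsive genes had 5 of 24 up (9 adjusted over the list alone; camera adjusted p = 2.85e-08), and lost the call with an estimated correlation (adjusted p = 0.0855). The study gene, glucose, respiratory chain, aminoacyl-tRNA synthetase and sleep-wake lists lost theirs as well (adjusted p = 0.0742, 0.252, 0.288, 0.405 and 0.111). The ZT0 count was 1206 among probe sets above the median level, 1401 with array weights and 185 with only the ZT0 arrays in the fit; it was 1018 with the spike-in batch as a block and 641 in the other 65 arrays. Without C57BL/6J control ZT0 replicate 3 it was 486, without C57BL/6J sleep-deprived ZT0 replicate 3 it was 1292 and without DBA/2J control ZT0 replicate 1 it was 475; the share that was higher, 73.5%, was 61.7% after quantile normalization, 63.5% with array weights, 80.6% with each array centred on its median and 85.4% with only the ZT0 arrays in the fit.

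At ZT6, after sleep deprivation over the first 6 h of the light phase, 4693 probe sets differed, 2309 higher and 2384 lower. Arc rose by 1.65, Hspa1b on an _x_at probe set by 1.55, Fos by 1.38, Egr2 by 1.34, Fosl2 by 1.18, Hspb1 on an _x_at probe set by 1.16, Npas4 by 1.04, the nuclear receptor gene Nr4a1 by 1.03 and Zmym1 by 1.02. Falls were led by Cirbp (-1.28), Rprd2 on an _s_at probe set (-1.01), 4930570G19Rik (-0.81), Opalin (-0.76), Btg1 (-0.75), 0610040B10Rik (-0.69), Dbp (-0.67), Slc22a8 (-0.66), Zfand4 (-0.58) and Eif2s3y (-0.54). Immediate early genes had 34 of 50 members up (36 up and 1 down adjusted over the list alone; camera adjusted p = 2.47e-47), heat shock 24 of 36 (25 adjusted over the list alone), endoplasmic reticulum stress 22 of 33 (23 adjusted over the list alone) and glucocorticoid-responsive genes 19 of 24 (21 adjusted over the list alone). Cholesterol synthesis had 13 of 27 down and 1 up (15 and 1 adjusted over the list alone; camera adjusted p = 1.06e-07). The sleep-wake, oligodendrocyte and olfactory bulb lists lost their calls with an estimated correlation (adjusted p = 0.108, 0.266 and 0.0811). The ZT6 count was 7558 with array weights, 5435 with the spike-in batch as a block and 3481 in the other 65 arrays.

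At ZT12, 4391 probe sets differed, 2119 higher and 2272 lower. Hspa1b on an _x_at probe set rose by 1.84, Arc by 1.58, Egr2 by 1.47, Fos by 1.25, Fosl2 by 1.22, Egr3 by 1.11, Npas4 by 1.01, Zmym1 by 0.99 and Hspa5 by 0.95. Opalin fell by 1.00, Rprd2 on an _s_at probe set by 0.87, Cirbp by 0.84, Krt12 by 0.61, Slc22a8 by 0.60, Btg1 by 0.58, 4930570G19Rik and 0610040B10Rik by 0.56 each, and Lss and Tnik by 0.55 each. Glucocorticoid-responsive genes had 20 of 24 members up (23 adjusted over the list alone; camera adjusted p = 4.35e-30), immediate early genes 35 of 50 (38 up and 1 down adjusted over the list alone), heat shock 24 of 36 (25 adjusted over the list alone) and endoplasmic reticulum stress 20 of 33 up with 1 down (25 and 1 adjusted over the list alone). Cholesterol synthesis had 14 of 27 down and 1 up (17 and 2 adjusted over the list alone; camera adjusted p = 5.47e-08). The oligodendrocyte list lost its call with an estimated correlation (adjusted p = 0.346). The count was 5493 with the spike-in batch as a block and 5339 in the other 65 arrays.

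At ZT18, 35 probe sets differed, 27 higher and 8 lower, and 2595 had an unadjusted p under 0.05. Besides Homer1, Egr2 rose by 0.60, Sdf2l1 by 0.49, Hspa1a by 0.43, Cdkn1a by 0.36, Fosl2 by 0.35, the deiodinase gene Dio2 by 0.30, Egr3 by 0.27, and Hsph1 and Tsc22d3 by 0.26 each. The falls were Zc3h6 (-0.33), Atp13a5 (-0.33), Ankrd12 (-0.29), Dbp on an _s_at probe set (-0.26), Marchf7 (-0.22), Exoc2 (-0.20), Rcor3 (-0.18) and Ypel5 (-0.15). As groups, heat shock genes shifted up with 5 of 36 called (20 adjusted over the list alone; camera adjusted p = 3.54e-29), immediate early genes with 3 of 50 (18 adjusted over the list alone; 1.02e-22), endoplasmic reticulum stress genes with 5 of 33 (13 adjusted over the list alone; 1.02e-22), glucocorticoid-responsive genes with 2 of 24 (7 adjusted over the list alone; 5.81e-18), sleep-wake genes with 1 of 34 (2 adjusted over the list alone; 2.47e-05) and hypothalamic markers with none of 7 (0.00417). With estimated correlation these lists stayed called, hypothalamic markers at an adjusted p of 0.0384. Among the genes named for ZT18, only Homer1, on its most responsive probe set, stayed called in every alternative applied to single genes and with each array left out. The call of Fosl2, for example, ended without any of 12 arrays. The count was 57 among probe sets above the median level, 88 with array weights, 10 with only the ZT18 arrays in the fit, 67 with the spike-in batch as a block, 51 in the other 65 arrays and from 9 to 48 with 1 array left out.

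**Figure D3:**
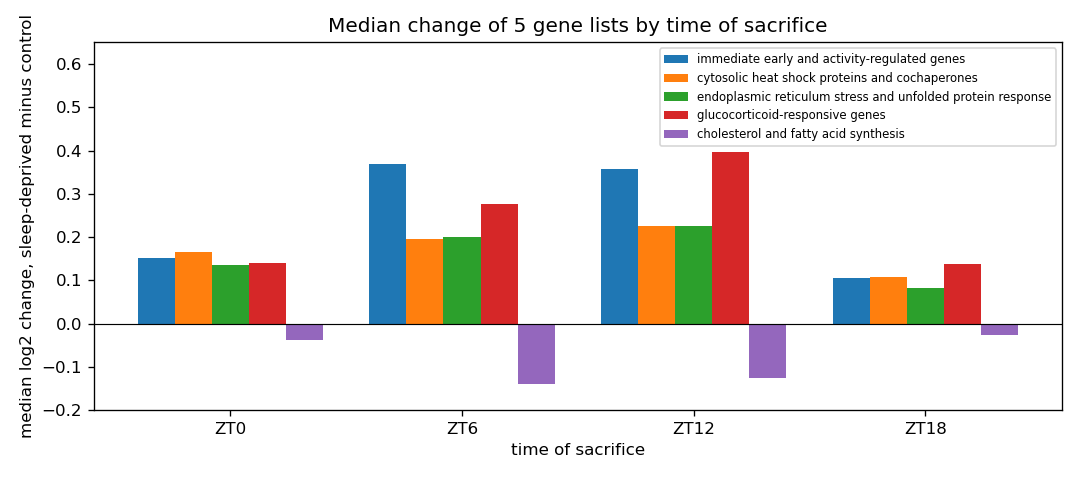
Bars give the median log2 change (sleep-deprived minus control) of the measured genes of 5 lists at each time of sacrifice, averaged over strains. The immediate early median was 0.15 at ZT0, 0.37 at ZT6, 0.36 at ZT12 and 0.10 at ZT18.

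The test of time by sleep deprivation, which asks whether the response differs between times of day, called 629 probe sets. Homer1 led with a range of 2.09 log2 units between its 4 effects (limma adjusted p = 5.68e-25). Hspa5 followed with 0.70 (7.8e-13), then Trim9, a ubiquitin ligase gene, with 0.48 (1.29e-12), Arc with 1.41 (6.19e-12), Cirbp with 1.13 (1.7e-11), Egr3 with 0.84 (3.09e-11), Fos with 1.18 (2.12e-10), Opalin with 0.75 (1.41e-09), Fosl2 with 0.88 (1.81e-09) and Nr4a1 with 0.86 (2.53e-09). Hspa5 means in controls were 11.32, 10.95, 10.98 and 11.80 at ZT0, ZT6, ZT12 and ZT18, and in sleep-deprived mice 11.88, 11.87, 11.92 and 12.05. Immediate early genes had 23 of 50 members called (28 adjusted over the list alone; Fisher's exact test adjusted p = 1.02e-25), endoplasmic reticulum stress 9 of 33 (16 adjusted over the list alone; 6.38e-08), glucocorticoid-responsive genes 8 of 24 (12 adjusted over the list alone; 6.38e-08) and heat shock 8 of 36 (12 adjusted over the list alone; 1.62e-06). In the heat shock list Hsph1 and Chordc1 had ranges of 0.37 and 0.47, and in the cholesterol list Lss had 0.49 (adjusted p = 0.000785). Clock genes had 3 of 23 called (7 adjusted over the list alone; 0.0396) and oligodendrocyte markers 2 of 9 (3 adjusted over the list alone; 0.0456). The study genes had 2 of 4 (3 adjusted over the list alone; 0.0114), and they were chosen by the study. Fisher's exact test takes genes as independent and was not set against other splits, so its p-values can be too small, above all those near 0.05. The count of probe sets was 1834 with array weights, 896 with the spike-in batch as a block and 576 in the other 65 arrays.

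In undisturbed controls, 5279 probe sets changed with time of day. Homer1 had the smallest p, with a range of 2.19 log2 units (limma adjusted p = 3.64e-34), followed by the clock genes Dbp (1.63; 1.36e-30), Ciart (1.41; 1.16e-25) and Per2 (1.34; 5.1e-25). Hspa5 (0.85), Trim9 (0.60), Arntl (0.76), Arc (1.73), Fos (1.48) and Cldn5, a tight junction gene of brain endothelium (0.70), completed the 10 smallest. Fos means were 9.13 ± 0.15 (SD within strain, n = 9) at ZT0, 7.64 ± 0.33 at ZT6, 7.75 ± 0.19 at ZT12 and 9.01 ± 0.20 at ZT18. Opalin means were 8.60, 8.99, 8.79 and 8.17 (range 0.82; adjusted p = 1.94e-16). Of 50 immediate early genes 34 changed (41 adjusted over the list alone; Fisher's exact test adjusted p = 5.92e-16), of 36 heat shock genes 25 (29 adjusted over the list alone; 2.55e-12), of 24 glucocorticoid-responsive genes 19 (20 adjusted over the list alone; 3.04e-11), of 23 clock genes 17 (21 adjusted over the list alone; 2.17e-09) and of 33 endoplasmic reticulum stress genes 20 (22 adjusted over the list alone; 1.08e-08). Hspa1b had a range of 1.62, Chordc1 of 0.66, Dusp1 of 0.88 and Sgk1, a glucocorticoid-induced kinase gene, of 0.90. Of 27 cholesterol synthesis genes 12 changed (14 adjusted over the list alone; 0.00101), among them Lss (0.47) and Insig1 (0.35). Among those called, 2073 probe sets peaked at ZT18, 1296 at ZT6, 1252 at ZT12 and 658 at ZT0. The count was 5828 with the spike-in batch as a block and 5099 in the other 65 arrays.

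In sleep-deprived mice, 639 probe sets changed with time of day, and 5 of the 6 smallest p belonged to clock genes: Dbp on an _s_at probe set (1.56; limma adjusted p = 3.97e-28), Arntl (0.77; 8.19e-23), Ciart (1.06; 1.01e-19), Nr1d2 (0.64; 1.38e-18) and Per2 (0.88; 1.8e-18). The other was that of Cldn5 (0.67; 1.01e-19). Homer1 had a range of 0.15 (adjusted p = 0.588). Tsc22d3, a glucocorticoid-induced gene, had a range of 0.72 (1.01e-16), and Sgk1 of 1.25 (6e-12). Of 24 glucocorticoid-responsive genes 19 changed (22 adjusted over the list alone; Fisher's exact test adjusted p = 4.15e-27), of 23 clock genes 16 (19 adjusted over the list alone; 1.62e-21), of 36 heat shock genes 8 (13 adjusted over the list alone; 4.45e-06) and of 50 immediate early genes 7 (23 adjusted over the list alone; 0.000433). Controls and sleep-deprived mice shared 456 of the called probe sets, where independent lists would share 74.9 if each probe set were equally likely to be called. An estimate of the mean variance between times was 0.303 times as large in sleep-deprived mice as in controls (0.000683 and 0.00226 log2 squared). This ratio was 0.234 to 0.475 with 1 array left out and 0.201 without the 6 arrays that stood apart. The sleep-deprived value is below what the error of a time mean alone would give, so these are not raw variances of time means. The count was 2533 with array weights, 722 with the spike-in batch as a block and 522 in the other 65 arrays.

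Arntl peaked at ZT0 and was lowest at ZT12 in controls (8.34 ± 0.10 and 7.58 ± 0.06; SD within strain, n = 9) and in sleep-deprived mice (8.52 ± 0.09 and 7.75 ± 0.07), with no detected difference in the response over time (limma adjusted p = 0.826). Dbp, on an _s_at probe set, and Ciart peaked at ZT12 in both. Per2 peaked at ZT18 in controls (7.70 ± 0.16) and at ZT12 in sleep-deprived mice (7.96 ± 0.09). The response differed with time for Per2 (adjusted p = 6.01e-06), Ciart (adjusted p = 0.00228) and Dbp on that _s_at probe set (adjusted p = 0.0264).

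**Figure D4:**
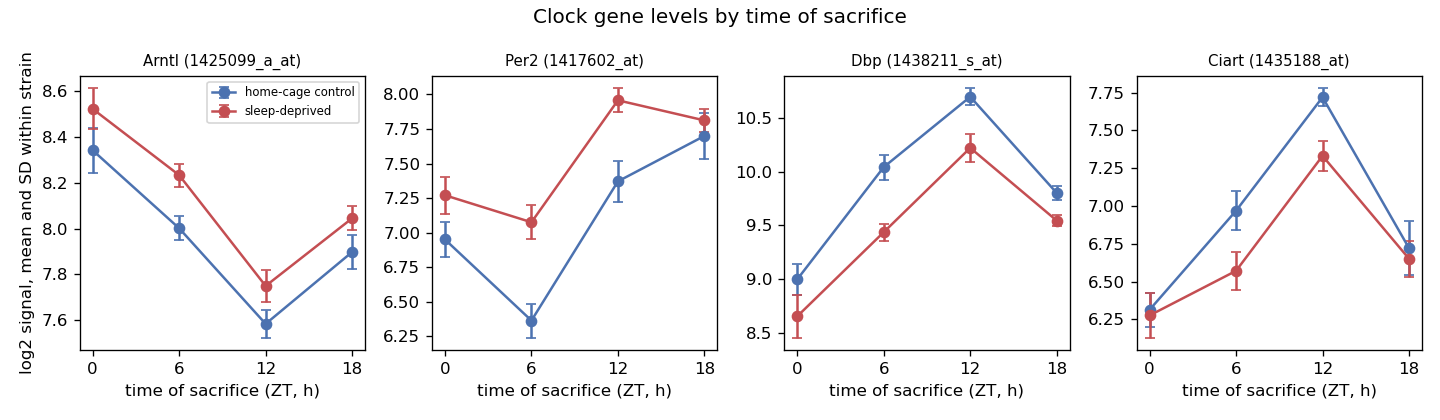
Points and bars give the mean and SD within strain of the log2 signal of Arntl, Per2, Dbp (an _s_at probe set) and Ciart against time of sacrifice (ZT, h) in home-cage controls (blue) and sleep-deprived mice (red), with 9 arrays per point and 8 at ZT18 after sleep deprivation. Per2 was 6.36 in controls and 7.07 in sleep-deprived mice at ZT6, against 7.70 and 7.81 at ZT18.

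Strains differed widely in undisturbed controls. Against AKR/J, C57BL/6J had 4386 probe sets higher and 5916 lower, 10302 in all. Prune2 was higher in C57BL/6J by 6.53 log2 units (limma adjusted p = 4.9e-62), Scn2b, a sodium channel subunit gene, by 6.44, Rpgrip1 by 5.19, Mtmr7 on an _s_at probe set by 4.62, Arhgap26 by 4.48, Pisd-ps3 by 4.11, Mir1931 by 4.10, the transcription factor gene Sox11 by 3.95, Uqcr10, a respiratory complex III gene, by 3.92 and Pttg1 on an _s_at probe set by 3.79. Lower in C57BL/6J were the G protein subunit gene Gnb1 (-3.07), the syndecan gene Sdc4 (-2.98), Pnpt1 (-2.92), the neurotrophin receptor gene Ntrk3 (-2.84), Tmem87a (-2.76), Supt16 (-2.54), Tra2a (-2.48), Cuedc1 (-2.24), AI506816 (-2.13) and Kbtbd11 (-2.09). Among list members, the sterol synthesis gene Sc5d was higher by 2.02 and the complement genes C1qc and C1qb of microglia by 1.18 and 1.03, while Kcnj9, a potassium channel gene, differed by -1.94, Gabra2 by -1.31 and the clock gene Per3 by -0.89. Where genes with a difference over 1 log2 unit had other probe sets (132 genes), these showed a median of 0.0535 of it.

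Against AKR/J, DBA/2J had 4056 probe sets higher and 3739 lower, 7795 in all. Scn2b was higher in DBA/2J by 6.40 (limma adjusted p = 9.05e-60), Uqcr10 by 4.15, the actin regulator gene Cap1 by 4.13, Pdxdc1 by 3.87, H2-D1, a class I histocompatibility gene, on an _x_at probe set by 3.81, Stab2 by 3.68, Pisd-ps3 on an _x_at probe set by 3.39, Gtpbp4 by 3.35, Vcp by 3.31 and Paip1 by 3.01. Gm13306 was lower (-5.68), as were Phgdh, an enzyme gene of serine synthesis, on an _x_at probe set (-4.79), Ssbp2 (-4.72), Tia1 (-4.36), Tmem267 (-4.27), Snhg14 (-3.12), Scmh1 (-3.03) and Camk2n1 (-3.01). Ptgs2 was lower in DBA/2J on both probe sets (-0.39 and -0.31; adjusted p = 0.000395 and 0.00197). Gabrb2, a GABA receptor subunit gene, differed by -1.25 and Cbln3, a cerebellar granule cell gene, by -1.28. Other probe sets of 150 genes showed a median of 0.0713 of the difference.

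Between DBA/2J and C57BL/6J, 6131 probe sets were higher and 4299 lower in DBA/2J, 10430 in all. Cap1 was higher in DBA/2J by 4.29 (limma adjusted p = 6.57e-40), H2-D1 on an _x_at probe set by 3.96, Pdxdc1 by 3.90, Stab2 by 3.75, Pnpt1 by 3.19, Paip1 by 3.13, Gnb1 by 3.09, Rbm45 by 3.02, and Xaf1 and, on an _x_at probe set, Serpina1b by 2.72 each. Lower were Prune2 (-6.28), Phgdh on an _x_at probe set (-4.84), Mtmr7 on an _s_at probe set (-4.59), Arhgap26 (-4.52), Tmem267 (-4.22), Mir1931 (-4.20), Ssbp2 (-4.13), Gm13306 (-4.13), Tia1 (-4.00) and Sox11 (-3.92). Ptgs2 differed by -0.47 and -0.44 (adjusted p = 1.88e-05 and 1.02e-05), Kcnj9 by 2.07, Gabra2 by 1.25, Per3 by 0.87, Sc5d by -2.01 and C1qc by -0.96. Other probe sets of 145 genes showed a median of 0.0456 of the difference. The 3 strain counts were 11332, 8149 and 11518 with the spike-in batch as a block and 10072, 7688 and 10997 in the other 65 arrays.

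**Figure D5:**
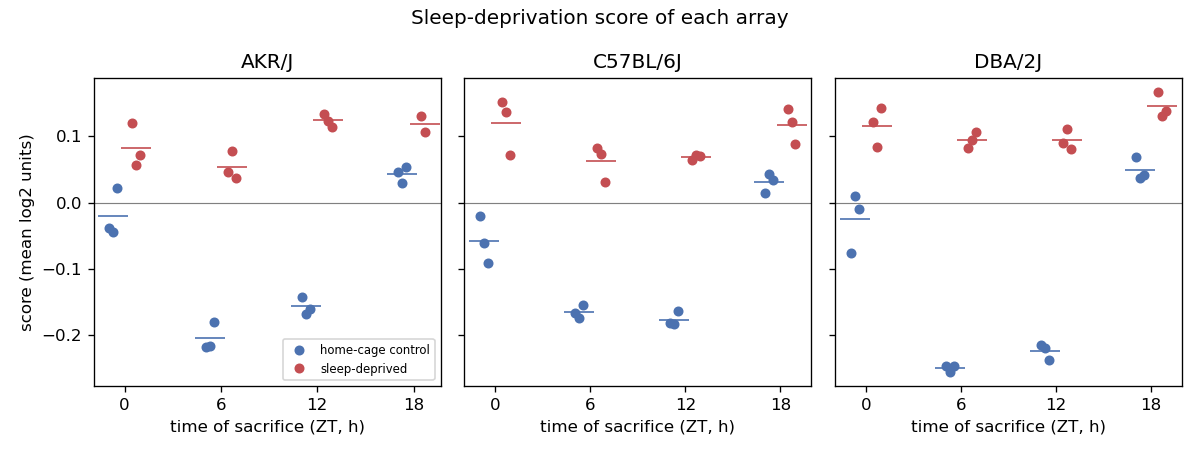
Each point is 1 array and each horizontal bar a group mean of a score in log2 units, the mean deviation from the strain mean over probe sets called with 1 sign in both other strains, taken with that sign, against time of sacrifice (ZT, h). Control means were -0.03 at ZT0, -0.21 at ZT6, -0.19 at ZT12 and 0.04 at ZT18, and sleep-deprived means lay between 0.07 and 0.13.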

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

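The tests of few calls at ZT18, the fits with the spike-in batch, the comparison with AKR/J and the changes without the 6 arrays at ZT6, and the count of list calls with an estimated correlation over other splits were chosen after the results were seen. Among the effects that differed between strains, the test of strain by sleep deprivation called 10 probe sets, with Gabra2 at an adjusted p of 0.000369, Ptgs2 at 0.00999, Pla2g4e at 0.0191, 4930570G19Rik, Mcm6 (an _x_at probe set) and 1500004A13Rik at 0.0237, and 4930578G10Rik and Rbm28 at 0.0367. The test of time by sleep deprivation called 629 probe sets, with Homer1 at an adjusted p of 5.68e-25, Hspa5 at 7.8e-13, Trim9 at 1.29e-12, Arc at 6.19e-12, Cirbp at 1.7e-11, Egr3 at 3.09e-11, Fos at 2.12e-10, Opalin at 1.41e-09, Fosl2 at 1.81e-09 and Nr4a1 at 2.53e-09.

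The counts were set against other splits or permutations of the arrays, 100 with the real one included. Chance can be excluded for the overall effect (real 7795, highest other 1025), AKR/J (2635 and 5), C57BL/6J (2907 and 249), DBA/2J (3106 and 2), the shared response (986 and 0), ZT0 (770 and 364), ZT6 (4693 and 134), ZT12 (4391 and 62) and ZT18 (35 and 1). It can be excluded for time by sleep deprivation (629 and 1), time of day in controls (5279 and 7) and in sleep-deprived mice (639 and 48), and the strain pairs (10302 and 2859, 7795 and 2366, 10430 and 790). In each of these 1 of the 100, the real one, was as large. For strain by sleep deprivation 2 of the 100 were as large (real 10, highest other 31). That met the bound written beforehand, but a permutation without a real interaction gave more calls than the real order. Chance is thus not firmly excluded for this count. Whether a structure of the samples gave the higher count was not tested. An earlier draw of permutations with another seed held no other one as large. Chance cannot be excluded for the count of gene lists called with camera's preset correlation: 11 of the 100 splits gave at least the real 8, and the highest other gave 12. With an estimated correlation the real count was 7 and the highest other 1, with 1 of 100 as large.

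C57BL/6J mice at ZT6 gave the most falls of the 12 strain-by-time comparisons, 2130 against 736 in DBA/2J (ratio 2.89) and 393 in AKR/J (ratio 5.42), and 2 of the 3 sleep-deprived arrays there were among the 6 that stood apart on spike-in controls. With this batch as a block the falls were 1251, 1069 and 455, ratios of 1.17 and 2.75; the first met the bound written beforehand, partly because the DBA/2J count rose, and the second, compared after the result was seen, did not, so a batch may account for part of the excess and whether it accounts for all of it stays open. Without the 6 arrays 120 falls were called in C57BL/6J at ZT6, where 1 sleep-deprived array was left and the median SE of the probe sets that fell went from 0.0885 to 0.110 log2 units, while their median change went from -0.33 to -0.22; they were chosen in this strain, the remaining array included, so that change is not independent of the choice. Their median change in the other strains averaged 0.152 of that in C57BL/6J (0.0229 in AKR/J and 0.281 in DBA/2J), and without the 6 arrays the shares were 0.247 and 0.429. A strain difference and the batch cannot be told apart here, since the AKR/J shares met the bound written for a strain difference, the DBA/2J shares lay between that bound and the one against it, and most of the arrays apart are of this strain.

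Sleep deprivation that ended at ZT18 gave few calls. Fewer arrays at ZT18 are argued against, since the lowest count at ZT6 with 1 array left out was 4043. None of the 6 arrays of the spike-in batch was at ZT18, so in the fit they could act on that count only through the shared spread. The ZT18 count without them was 51, which could hardly have come out otherwise and is no separate evidence against the batch. The score of the sleep deprivation response in controls was higher at ZT18 than at ZT6 by 0.247 (n = 9 and 9; exact permutation p = 0.00025, two-sided, the smallest possible), and in sleep-deprived mice by 0.0575 (n = 8 and 9; exact permutation p = 0.00025). These values are consistent with controls at ZT18 that were already near the sleep-deprived level, and remain a hypothesis since the ZT18 result was seen first.

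Strain differences of over 1 log2 unit in controls may come from sequence differences under the probes. Other probe sets of the same genes showed a median share of 0.0535 of the difference (median of the 3 pairs), against 0.530 for other probe sets of genes changed by sleep deprivation by over 0.25 log2 units. The thresholds of these shares thus differ. Both shares used probe sets above the median level, with the probe set of largest difference per gene as reference. C57BL/6J was the higher strain in 64.9% of such differences against AKR/J and in 64.9% against DBA/2J, whereas DBA/2J was higher than AKR/J in 49.1%, as probes designed near the C57BL/6J sequence predict for large differences. Over all called probe sets the direction was the opposite, with C57BL/6J higher in 42.6% against AKR/J and DBA/2J higher than C57BL/6J in 58.8%, so this explanation is not offered for the smaller differences. These shares kept their direction but were nearer to even under other scalings. They were 47.7% and 53.2% after quantile normalization, and 45.5% and 53.2% with each array centred on its median. A true difference in the levels of single genes stays open, as it was not tested with another assay.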

How the results depend on the processing

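The fits with the spike-in batch, without its 6 arrays and with the pituitary covariate were chosen after seeing the data. Of 558 named gene results 434 were called; 384 of these stayed called in every setting and with each array left out, 50 lost the call in 1 or more, and none reversed. Values are counts of called probe sets. Quantile normalization gave 16 for strain by sleep deprivation, and the share higher at ZT0 was 61.7% against 73.5%, with 63.5% for array weights, 80.6% for centring on medians and 85.4% with only the compared groups. Only probe sets above the median level gave 1206 at ZT0 and 57 at ZT18. Array weights gave 4998 in C57BL/6J, 1401 at ZT0, 7558 at ZT6, 88 at ZT18, 60 for strain by sleep deprivation, 1834 for time by sleep deprivation and 2533 for time of day in sleep-deprived mice. The pituitary covariate gave 18 for strain by sleep deprivation. Only the compared groups in the fit gave 185 at ZT0 and 10 at ZT18, with fewer arrays behind the spread. The batch as a block gave 67 at ZT18, and leaving out its 6 arrays gave 1889 in C57BL/6J. The cause was not tested for the others.

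With 1 probe set per gene, fewer were tested: 4350 for the mean effect, 1625, 1852 and 1890 in AKR/J, C57BL/6J and DBA/2J, 2722 at ZT6, 2686 at ZT12, 3008 for time of day in controls, and 4752, 3458 and 4835 for C57BL/6J against AKR/J, DBA/2J against AKR/J and DBA/2J against C57BL/6J. A minimum of 0.25 log2 left 356 for the mean effect, 469, 494 and 521 by strain, 174 shared, 206, 1337, 1220 and 18 at ZT0, ZT6, ZT12 and ZT18, 1868 for time of day in controls, 338 in sleep-deprived mice, and 3607, 3168 and 3793 for the strain pairs in the same order. Of 28 lists, fry, which does not compare with other genes, called 14. The oligodendrocyte list lost its call with probe sets above the median (adjusted p = 0.104), array weights (0.0653), estimated correlation (0.449), the mean of all probe sets (0.238), the batch block (0.0549) and without the 6 arrays (0.0739), and the study genes with probe sets above the median (0.0664).

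With 1 array left out, counts ranged from 7275 to 7871 for the mean effect, 1878 to 3021 in AKR/J, 2335 to 3603 in C57BL/6J, 2654 to 3255 in DBA/2J, 822 to 1030 shared, 475 to 1292 at ZT0, 4043 to 5184 at ZT6, 3855 to 4524 at ZT12, 9 to 48 at ZT18, 6 to 25 for strain by sleep deprivation, 458 to 757 for time by sleep deprivation, 4739 to 5768 for time of day in controls, 486 to 931 in sleep-deprived mice, 9749 to 10513, 7321 to 8053 and 9878 to 10583 for the strain pairs, and 7 to 8 lists. The ZT0 count was 486 without C57BL/6J control ZT0 replicate 3, 1292 without C57BL/6J sleep-deprived ZT0 replicate 3 and 475 without DBA/2J control ZT0 replicate 1. The ZT18 count was, at ZT18, 20 without AKR/J control replicate 2, 9 and 13 without AKR/J sleep-deprived replicates 1 and 2, 18 without C57BL/6J control replicate 1, 15 without C57BL/6J sleep-deprived replicate 1, 17 and 21 without DBA/2J control replicates 2 and 3, and 23 without DBA/2J sleep-deprived replicate 3. The strain by sleep deprivation count was 20 without AKR/J control ZT0 replicate 2, 22 and 20 without AKR/J control ZT6 replicates 1 and 2, 6 and 18 without AKR/J sleep-deprived ZT6 replicates 1 and 3, 25 without C57BL/6J control ZT0 replicate 3, 21 without C57BL/6J control ZT12 replicate 1, 17 without C57BL/6J control ZT18 replicate 2, 22 without C57BL/6J sleep-deprived ZT6 replicate 2, 6 without DBA/2J control ZT0 replicate 1 and 6 without DBA/2J sleep-deprived ZT0 replicate 3. A group left with 1 array is assumed to vary like the others.

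Replicate numbers gave no clear pairing of the arrays. Of 35 same-numbered pairs of control and sleep-deprived arrays, 6 had deviations that correlated over 0.1, and pair correlations ran from -0.275 to 0.603. The mean was 0.00839 for the same number and -0.00417 for another. Of 71 arrays, 33 correlated best with their own number. The number to be found without pairing was not computed, so some pairing is not excluded. Most of the 6 arrays that stood apart on spike-in controls carried replicate number 3, so the number is not free of that batch. The replicate block gave 7837 for the mean effect, 2623, 2979 and 3174 by strain, 1013 shared, 807, 4794, 4500 and 40 by time, 14 and 653 for the interactions, 5418 and 636 for time of day, 10441, 7874 and 10532 for the strain pairs, and 8 lists. The alternative of log2 of the value plus 16 was not run, since the values are log2 already. Signal over background could not be set, as no detection calls were used here.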

Other observations

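The 10 smallest p for time of day in sleep-deprived mice also included Cldn5, Fabp7, Mmp14 and Fmo2. Cldn5, a tight junction gene of brain endothelium, had control means of 9.06, 8.94, 8.36 and 8.93 log2 units at ZT0, ZT6, ZT12 and ZT18 and sleep-deprived means of 9.00, 8.77, 8.33 and 8.90 (limma adjusted p for time of day = 1.26e-21 and 1.01e-19). Fabp7, a fatty acid binding protein gene of astrocytes, had control means of 10.88, 10.93, 10.51 and 10.34 and sleep-deprived means of 11.00, 11.16, 10.47 and 10.33 (range in sleep-deprived mice 0.83; adjusted p = 1.04e-16). Mmp14, a matrix metalloproteinase gene, was highest at ZT0 (6.88 and 6.90) and lowest at ZT12 (6.24 and 6.10; adjusted p in sleep-deprived mice = 1.78e-15). Fmo2, a monooxygenase gene, went the other way, from 4.00 at ZT0 to 4.55 at ZT12 in controls and from 4.09 to 4.82 in sleep-deprived mice (adjusted p = 7.96e-15). The marker lists that follow were tested with genes taken as independent, so their p-values can be too small. Among endothelial markers, 5 of 9 changed with time in controls (6 adjusted over the list alone; Fisher's exact test adjusted p = 0.0161) and 2 of 9 in sleep-deprived mice (3 adjusted over the list alone; 0.0478). Among meningeal markers these were 5 of 9 (5 adjusted over the list alone; 0.0161) and 3 of 9 (4 adjusted over the list alone; 0.0036). Olfactory bulb markers had 4 of 6 called in controls (4 adjusted over the list alone; 0.0161) and none of 6 in sleep-deprived mice (none adjusted over the list alone; 1); the test of time by sleep deprivation called 1 of the 6 (2 adjusted over the list alone; 0.304). Oligodendrocyte markers had 5 of 9 called in controls (6 adjusted over the list alone; 0.0161) and 2 of 9 in sleep-deprived mice (5 adjusted over the list alone; 0.0478), and their precursors 4 of 7 (5 adjusted over the list alone; 0.0276) and 2 of 7 (3 adjusted over the list alone; 0.0383). Astrocyte markers did not pass the test in either condition, with 2 of 10 called in controls (3 adjusted over the list alone; 0.668) and 1 of 10 in sleep-deprived mice (2 adjusted over the list alone; 0.381), nor did microglial markers, with none of 10 called in either (2 and 1 adjusted over the list alone; 1 and 1).

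Arrays of 1 group were compared for the deviations of Cirbp, of the heat shock list and of the immediate early list from their group means, 3 relations over 71 arrays with within-group permutations. Cirbp against heat shock had Pearson r = -0.369 (permutation p = 0.0213, adjusted 0.0532) and Spearman rho = -0.339 (p = 0.0194, adjusted 0.0327), r = -0.270 without the 2 farthest arrays and -0.499 in the 65 arrays of 1 spike-in batch. Cirbp against immediate early genes had r = -0.141 (permutation p = 0.408, adjusted 0.408), rho = -0.310 (p = 0.0296, adjusted 0.0327), r = -0.363 without the 2 farthest arrays and -0.0670 in the 65 arrays. Immediate early against heat shock genes had r = 0.288 (permutation p = 0.0355, adjusted 0.0532), rho = 0.305 (p = 0.0327, adjusted 0.0327), r = 0.337 without the 2 farthest arrays and 0.300 in the 65 arrays. Pools in which chaperone RNA was higher may have lower Cirbp RNA, but the tests leave each of the 3 relations open. The bound written beforehand counted a missed p threshold as evidence against a relation; that was wrong, since a missed threshold excludes nothing, and it was replaced after the result was seen by a bound on r.

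S100a8, a neutrophil gene measured on an _s_at probe set, was highest in DBA/2J sleep-deprived ZT18 replicate 3 (9.12 log2 units) and DBA/2J control ZT0 replicate 3 (8.88), with the next array at 7.01. Omp, a gene of olfactory sensory neurons, was highest in C57BL/6J control ZT18 replicate 2 (7.73), with the next array at 6.50.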
